A study of Rattus norvegicus with 8 samples.

How the data were processed

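The series holds 8 rat samples. Of these, 6 are bulk RNA-seq libraries of cultured neonatal ventricular cardiomyocytes, isolated from newborn rats on postnatal day 1 per the labels' protocols and transfected with a small interfering RNA at 50 nM for 36 h. The groups are si-Control, si-Atf3 and si-Jun, with 2 replicates each. The labels do not say whether the replicates of a group are separate cultures. The other samples are single-cell libraries of heart tissue, 1 from postnatal day 1 and 1 from postnatal day 7, prepared with the 10x Genomics protocol per the labels' protocols. The design text of the series speaks of cultured cardiomyocytes for these, whereas the sample labels give heart with cardiomyocytes and non-myocytes, and the libraries are treated here as heart cells.

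The bulk table deposited by the authors gives counts per 1000000 (CPM) for 28909 genes, named by symbol. HISAT2 2.1.0, StringTie 1.3.4, edgeR 3.20.9 and the build rn6 are named in the submitters' processing notes, which do not say which step made the table. The columns headed NC were read as si-Control, the only group left for them. Each column of deposited CPM sums to 1000000, and 100% of its values are whole multiples of 1 step within a tolerance of 0.05 reads, so whole reads were recovered from the steps. The recovered totals were 66.2 and 69.5 M reads for si-Control, 79.1 and 65.5 M for si-Atf3, and 58.8 and 66.0 M for si-Jun, taking replicate 1 first. The single-cell matrices deposited by the authors hold raw UMI counts for 25399 genes, and Cell Ranger 3.1.0, STAR and rn6 are named in the submitters' processing notes. They list 10578 barcodes at day 1 and 14174 at day 7. Of their symbols, 125 belong to more than 1 gene, and for these the gene with the most UMIs was used. Gene symbols were taken as the deposited tables give them, and no genome or annotation was used.

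Bulk values were analysed as log2(CPM + 1) with limma 3.58.1 (R 4.3.3) and a mean-dependent prior variance, in 1 fit of all 6 libraries, so that the groups of 2 share an estimate of the spread. Genes at 1 CPM or more in at least 2 libraries entered, which left 13856. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The comparisons were si-Atf3 against si-Control, si-Jun against si-Control, and si-Atf3 against si-Jun, which tests the difference between the siRNA groups. For genes called in both groups against si-Control, 50 simulations drew all 6 libraries without group differences. Both simulated groups shared the simulated controls, and each gene was drawn independently. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

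Before the data were examined, 22 gene lists and 15 lists of cell type markers were fixed. The gene lists covered adult sarcomere isoforms, fetal-type contractile and natriuretic genes, calcium handling, ion channels, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, the tricarboxylic acid cycle, glycolysis, the cell cycle (G1 and S, and G2 and M), the AP-1 family, immediate early genes, the amino acid and unfolded protein responses, the interferon response, cytokines, collagens and matrix, cholesterol synthesis, p53 targets, cardiac transcriptional regulators, AP-1-linked targets and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. A list of fewer than 5 measured genes was not tested. Some list members do not appear in the bulk table under the symbol fixed and were not analysed here, among them Tcap, Cd36, E2f1 and Ccnb2. From the single-cell libraries, the 200 genes with the highest and the 200 with the lowest day 7 over day 1 ratio in cardiomyocyte-like cells, out of 4382 eligible genes, were tested in the bulk comparisons in the same way.

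Barcodes with at least 500 genes and at most 40% mitochondrially encoded UMIs were kept. Scrublet's automatic threshold (scanpy 1.11.5, scikit-image 0.26.0, Python 3.11.15) marked 1 barcode in each library, so the highest-scoring 0.8% per 1000 barcodes were removed as doublets under a rule fixed beforehand, 295 at day 1 and 319 at day 7. This kept 5780 cells at day 1 and 5991 at day 7, with medians of 13799 and 13994 UMIs. Counts were scaled to 10000 per cell and log-transformed. Both libraries were clustered together without integration on 2000 variable genes, 30 principal components and 15 neighbours, with leidenalg 0.10.2 at resolution 1. A cluster took the name of a cell class when at least 3 of its markers were over 2-fold above the other clusters and at 10 CPM or more, when that class led the next by a share of 0.1 of its markers, and when its 10 leading genes held no more markers of another class. Low-UMI clusters, with a median under 1/3 of their library's, and with no marker of their own among the leading genes were left unnamed, a step added after the data were seen. These classes are called cardiomyocyte-like, fibroblast-like and so on. Values are CPM of UMIs summed over the cells of a class and library. Intervals are exact at 95%, Clopper-Pearson for shares and Poisson for CPM, and cover counting error only. With 1 library per day no test of the days was made. A gene counted as different when its ratio was over 2 or under 0.5, its level at least 20 CPM on the higher day and its intervals apart. A list is described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size and expression. A list of fewer than 5 compared genes was left out.

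Named genes followed a rule fixed before the data were examined. In the bulk libraries these are both targets, then the 10 largest rises and falls among called genes with a mean of 5 CPM, both replicates on the same side of both replicates of the other group, and no provisional name. Where fewer than 3 passed, the 5 largest at an unadjusted p under 0.05 are given and said not to pass. For si-Atf3 against si-Jun these are the 5 largest in each direction. From each list they are up to 4 members with the smallest p. In the single cells they are the AP-1 genes, the 10 largest and 10 smallest ratios in cardiomyocyte-like cells among genes at 50 CPM or more on the higher day, 4 each in other classes, and the most abundant list members.

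On log2 values simulated gene by gene with the fitted spread, limma found 69 of 100 genes changed 2-fold and 97 of 100 changed 4-fold. This was for si-Atf3 against si-Control, with 11 false calls among 13856 genes. edgeR found 25 and 94 of 100, with 12 false calls among 16349 genes. The camera test found the 1 changed list with 0 false calls. Its genes were drawn independently, so this leaves untested the calls of lists whose members move together. In the data the estimated correlation was 0.62 for G1 and S phase genes and 0.91 for G2 and M phase genes. The 2-fold rule found 200 of 200 genes changed 4-fold in simulated sums of cardiomyocyte-like cells, with 0 false calls among 4188 genes. Alternatives covered the pseudocount, filters on low values, other scalings, the replicate number as a block, fits of 4 libraries, left-out libraries, set sizes, the mitochondrial and gene limits, doublets, clustering, the CPM total and thinning of each cell to 2000 UMIs. The closing section gives their effect.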

Results

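The data cover transcript levels in 8 rat samples. In 6 of them, cultured neonatal ventricular cardiomyocytes were transfected with a control siRNA, an siRNA against Atf3 or an siRNA against Jun, with 2 libraries each. Atf3 and Jun encode leucine zipper transcription factors of the AP-1 family. Bulk depth ranged from 58.8 to 79.1 M recovered reads per library. The other samples are 1 single-cell library of the heart from postnatal day 1 and 1 from day 7, with 5780 and 5991 cells kept. The title of the series places the comparisons in postnatal maturation of cardiomyocytes. The si-Control libraries lay at −14.2 and −42.9 on the first principal component of the bulk values, which held 39.1% of the variance, and the 4 other libraries lay between 6.45 and 21.0.

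Atf3 was lower in both si-Atf3 libraries than in the others, and Jun was not clearly lower in the libraries labelled si-Jun. Atf3 stood at 19.3 ± 0.748 CPM (SD, n = 2) in si-Control, 11.4 ± 1.10 CPM in si-Atf3 and 17.6 ± 0.842 CPM in si-Jun. The single si-Atf3 libraries held 12.2 and 10.6 CPM, against 18.8 and 19.8 CPM in si-Control. The log2 fold change of Atf3 in si-Atf3 against si-Control was −0.72 (SE 0.145), with an unadjusted p of 0.0022 and an adjusted p of 0.253 in limma with Benjamini-Hochberg adjustment over all genes. Jun stood at 91.3 and 97.8 CPM in si-Control, 91.7 and 101 CPM in si-Atf3, and 94.9 and 75.4 CPM in the libraries labelled si-Jun. Its log2 fold change in those was −0.16 (SE 0.139; limma adjusted p = 0.656). Protein levels were not measured, so the si-Jun libraries are named by their label throughout, and any direction drawn from them rests on that label.

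**Figure D1:**
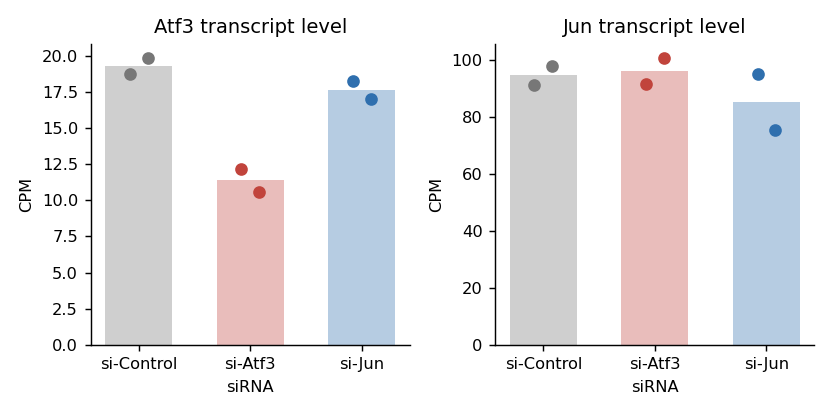
CPM of Atf3 (left) and Jun (right) by siRNA; points are single libraries and bars are means of 2 libraries. Atf3 is at 12.2 and 10.6 CPM in si-Atf3 and between 17.0 and 19.8 CPM elsewhere, while Jun in one library labelled si-Jun (94.9 CPM) lies within the si-Control values.

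The comparison of si-Atf3 with si-Control asks which transcripts respond to lowering Atf3. Cell cycle and cholesterol genes were higher and fatty acid oxidation, interferon, cytokine and immediate early genes were lower. The list of G1 and S phase genes rose, with a median log2 fold change of 0.93 over 39 measured genes (limma camera with Benjamini-Hochberg adjustment over the lists, adjusted p = 9.90e-20; adjusted p = 0.406 with an estimated correlation). Mcm3, a subunit of the replicative helicase, had 26.6 ± 2.31 CPM in si-Control and 82.3 ± 2.31 CPM in si-Atf3 (SD, n = 2), a log2 fold change of 1.60 (SE 0.259). Dtl (1.96), which targets replication factors for degradation, Cdc45 (1.37) and Mcm2 (0.93), both of the helicase, followed. No gene of any list passed over all genes, and 31 of these 39 passed when adjusted over the list alone. The list of G2 and M phase genes rose too, with a median of 0.85 over 44 genes, all of them above 0 (camera adjusted p = 6.97e-14; adjusted p = 0.435 with an estimated correlation). Its members Ckap2l (1.28), Mki67 (1.35), Top2a (1.34) and Aurkb (1.09) had an unadjusted p under 0.05 with 18 others, and 0 of the 44 passed adjusted over the list alone in limma.

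Cholesterol synthesis and uptake rose in si-Atf3 with a median of 0.75 over 22 genes (limma camera adjusted p = 3.28e-10; adjusted p = 0.435 with an estimated correlation), and 10 members passed adjusted over the list alone. Examples are Mvd (0.74), an enzyme of the mevalonate pathway, and Srebf2 (0.63), the pathway's transcription factor. Fatty acid uptake and oxidation fell with a median of −0.34 over 29 genes, 27 of them below 0 (adjusted p = 4.47e-13; adjusted p = 0.406 with an estimated correlation), and 12 passed adjusted over the list alone. Acaa2, the last enzyme of mitochondrial beta-oxidation, had 151 ± 12.1 CPM in si-Control and 78.2 ± 2.31 CPM in si-Atf3 (log2 −0.94, SE 0.162). Lpl (−0.79), the lipase that frees fatty acids at the vessel wall, Decr1 (−0.78) and Acot2 (−0.69) lay in the same direction. Fetal-type contractile and natriuretic genes rose with a median of 0.32 over 15 genes (adjusted p = 0.0119; adjusted p = 0.435 with an estimated correlation; without si-Control replicate 1 the median was 0.16 and camera's adjusted p 0.381). The smooth muscle gene Cnn1 (2.69), skeletal actin Acta1 (1.65) and the atrial light chain Myl4 (0.91) were among its members with the smallest p values.

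Lists of stress and inflammation fell in si-Atf3. Among them only the interferon response had a larger fall in its median than the reference list of ribosomal proteins described below (−0.27). The interferon response had a median of −0.30 over 28 genes (limma camera adjusted p = 3.96e-07; adjusted p = 0.435 with an estimated correlation), with the chemokines Cxcl11 (−1.52) and Cxcl10 (−1.09), the GTPase Gbp2 (−0.75) and the antiviral Rsad2 (−0.62), and 1 member passed adjusted over the list alone. Cytokines and acute inflammation had a median of −0.25 over 24 genes (adjusted p = 5.64e-06; adjusted p = 0.406 with an estimated correlation), including complement C3 (−0.67), Ccl2 (−0.72) and Spp1 (−0.67). Macrophage markers fell as well, with a median of −0.52 over 10 genes (adjusted p = 1.11e-05; adjusted p = 0.420 with an estimated correlation), among them the complement genes C1qc (−1.11) and C1qa (−0.87). A smaller share of macrophages cannot be told apart from a lower response in these lists, and neither was tested. Immediate early genes without AP-1 members had a median of −0.25 over 26 genes (adjusted p = 9.40e-06; adjusted p = 0.406 with an estimated correlation), with Klf2 (−0.78), Egr2 (−0.58), Zfp36 (−0.47) and Sgk1 (−0.35). The AP-1 family itself had a median of −0.19 over 20 genes (adjusted p = 0.00135; adjusted p = 0.406 with an estimated correlation), with Maff (−0.68), Junb (−0.62) and Jund (−0.45) beside Atf3; without si-Control replicate 1 its median was −0.23 and camera's adjusted p 0.0657. AP-1-linked targets had a median of −0.21 over 24 genes (adjusted p = 0.00379; adjusted p = 0.406 with an estimated correlation), with the intermediate filament gene Vim (−0.53) and Tnfrsf12a (−0.42); without si-Control replicate 2 the median was −0.10 and camera's adjusted p 0.0510. Without 1 library the interferon median ran from −0.51 to −0.13 and that of cytokines from −0.47 to −0.16, without si-Control replicate 2 those of immediate early genes and the AP-1 family were −0.14 and −0.33, and all 4 still passed with camera there.

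Adult sarcomere isoforms did not pass in si-Atf3, and oxidative phosphorylation had a median near 0. The list of ribosomal proteins had been fixed as a reference with no change in view, and it passed. A call by camera at the preset correlation therefore need not mark a response. The reference list of ribosomal proteins fell by a median of 0.27 over 33 genes (limma camera adjusted p = 1.19e-07; adjusted p = 0.550 with an estimated correlation; −0.06 without si-Control replicate 2, adjusted p = 0.102). Nuclear-encoded oxidative phosphorylation had a median of −0.05 (adjusted p = 0.0497; adjusted p = 0.951 with an estimated correlation), which turned to 0.14 without si-Control replicate 2. The lists that did not pass were adult sarcomere isoforms (0.30, adjusted p = 0.0868), mitochondrially encoded genes (−0.16, 0.0710), collagens and matrix (0.04, 0.114), cardiac transcriptional regulators (0.14, 0.492), glycolysis (0.12, 0.508), the amino acid and unfolded protein responses (0.03, 0.764), the tricarboxylic acid cycle (0.10, 0.838), ion channels (0.08, 0.869), p53 targets (0.03, 0.869) and calcium handling (−0.02, 0.990). Camera ranked p53 targets and the amino acid response downward although their medians were above 0, and the mean of the calcium handling list (0.03) had the sign opposite to its median. Cardiomyocyte markers rose, with a median of 0.63 over 7 genes (adjusted p = 1.67e-04; adjusted p = 0.191 with an estimated correlation), for example the myosin-binding protein gene Mybpc3 (0.68) and cardiac actin Actc1 (0.63). With fry, cardiomyocyte markers passed (adjusted p = 0.0266) and 0 of the 22 gene lists did, against 12 with camera.

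Single genes that passed in si-Atf3 numbered 12, 6 higher and 6 lower, among 13856 tested with limma and Benjamini-Hochberg adjustment, and 1766 had an unadjusted p under 0.05. edgeR called 5 higher and 7 lower and DESeq2 298 higher and 202 lower. Lilrb3a, an inhibitory receptor of myeloid cells, fell from 13.9 and 15.0 CPM in si-Control to 0.784 and 0.580 CPM (log2 −3.20, SE 0.238, limma adjusted p = 0.0087). Hnrnpab, an RNA-binding protein gene, was listed at 0 in both si-Control libraries and stood at 164 and 172 CPM in si-Atf3 (limma adjusted p = 5.57e-06). The splicing factor gene Wbp11 stood at 34.5 and 37.4 CPM in si-Control and was listed at 0 in both si-Atf3 libraries (limma adjusted p = 2.25e-04). The antiviral gene Oas1g was listed at 0 in si-Control and stood at 11.2 and 8.33 CPM (limma adjusted p = 0.0480), and Sccpdh stood at 1.43 CPM and 0 in si-Control and at 36.8 and 35.6 CPM in si-Atf3 (limma adjusted p = 0.0211). The other called genes carry provisional names. Among them is AC111885.1, at 107 and 120 CPM in si-Control and 1.05 and 0.412 CPM in si-Atf3 (limma adjusted p = 5.87e-04). Of the 15 genes called in any comparison, 13 were listed at 0 in at least 1 library, all but Lilrb3a and AC111885.1. Without such all-or-none genes, 114 in number, the counts were 0 higher and 2 lower in limma. Without 1 library they ran from 4 to 537 higher and from 7 to 153 lower, the highest without si-Control replicate 1.

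Penk, which encodes the precursor of enkephalins, stood at 272 ± 85.9 CPM in si-Control and 66.9 ± 3.47 CPM in si-Atf3 (SD, n = 2; log2 −1.97, SE 0.239, limma adjusted p = 0.115), which did not pass. Reg3b (−1.88, limma adjusted p = 0.205), a secreted lectin, the imprinted gene Mest (−1.54, 0.285), the chemokine gene Cxcl13 (−1.73, 0.335) and complement C4a (−2.84, 0.359) also did not pass.

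The comparison of the libraries labelled si-Jun with si-Control showed higher cell cycle and cholesterol genes and lower fatty acid oxidation genes. G2 and M phase genes rose with a median of 1.17, and all 44 were above 0 (limma camera adjusted p = 7.46e-21; adjusted p = 0.603 with an estimated correlation). Of these, 40 passed adjusted over the list alone, among them Ckap2l (1.57), the proliferation marker Mki67 (1.59), topoisomerase Top2a (1.56) and Cdca2 (1.49). Top2a stood at 48.6 ± 3.11 CPM in si-Control and 159 ± 94.2 CPM in the libraries labelled si-Jun (SD, n = 2), which differed widely from each other. G1 and S phase genes rose with a median of 0.75 (camera adjusted p = 2.86e-14; adjusted p = 0.603 with an estimated correlation), and 6 passed adjusted over the list alone. Rrm2 (2.00), a subunit of ribonucleotide reductase, Dtl (1.58), Mcm3 (1.12) and Cdc45 (1.04) had the smallest p values. Cholesterol synthesis and uptake rose with a median of 0.73 (adjusted p = 1.30e-09; adjusted p = 0.667 with an estimated correlation), 5 genes passed adjusted over the list alone, and Mvd (0.70) and Srebf2 (0.57) were among its members with the smallest p values. Without si-Jun replicate 1 the medians were 0.59 for G2 and M phase, 0.35 for G1 and S phase and 0.29 for cholesterol genes, and all 3 lists still passed with camera.

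Fatty acid uptake and oxidation fell in the libraries labelled si-Jun with a median of −0.35 (limma camera adjusted p = 1.05e-14; adjusted p = 0.603 with an estimated correlation), and 10 of 29 genes passed adjusted over the list alone. Acaa2 (−0.91, SE 0.162), Decr1 (−0.78) and Lpl (−0.74) are examples. The amino acid and unfolded protein responses rose with a median of 0.31 over 29 genes (adjusted p = 2.10e-05; adjusted p = 0.667 with an estimated correlation; 0.24 without si-Control replicate 1, adjusted p = 0.136), with the amino acid transporter gene Slc7a5 (0.68), Sesn2 (0.78), Mthfd2 (0.73) and Sdf2l1 (0.46). Immediate early genes fell with a median of −0.18 (adjusted p = 2.07e-04; adjusted p = 0.603 with an estimated correlation), with Egr2 (−1.07), Cyr61 (−0.84) and Hspa1a (−0.63), while Socs3 was at 0.46. AP-1-linked targets fell with a median of −0.21 (adjusted p = 0.0288; adjusted p = 0.603 with an estimated correlation; −0.03 without si-Control replicate 2, adjusted p = 0.191, and −0.11 without si-Jun replicate 2, adjusted p = 0.0739), with the matrix protease gene Mmp9 (−1.07), Spp1 (−0.60) and Sphk1 (−0.52), while Cd44 was at 0.41. Ribosomal proteins fell with a median of −0.20 (adjusted p = 5.20e-06; adjusted p = 0.761 with an estimated correlation), a median of 0.0012 without si-Control replicate 2. Immediate early genes had a median of −0.35 without si-Control replicate 1 and −0.042 without replicate 2, and the amino acid response 0.20 without si-Jun replicate 1.

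The other 14 lists did not pass in the libraries labelled si-Jun under limma's camera. The AP-1 family had a median of −0.10 (adjusted p = 0.106), calcium handling −0.11 (0.106), oxidative phosphorylation −0.05 (0.0700), mitochondrially encoded genes −0.07 (0.429) and the tricarboxylic acid cycle 0.02 (0.429). Interferon response was at 0.11 (0.236), cytokines at −0.06 (0.303), p53 targets at 0.19 (0.138), glycolysis at 0.26 (0.236), collagens at 0.06 (0.456), fetal-type genes at 0.10 (0.540), ion channels at 0.03 (0.567), adult sarcomere at 0.02 (0.786) and regulators at 0.03 (0.993). Cardiomyocyte markers were at 0.14 (0.107) and macrophage markers at −0.13 (0.208). Camera ranked ion channels and the tricarboxylic acid cycle downward. Their means were −0.06 and −0.02, while their medians were above 0. With fry 0 of the 22 lists passed, against 8 with camera.

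Single genes that passed in the libraries labelled si-Jun numbered 10, 4 higher and 6 lower, in limma with Benjamini-Hochberg adjustment, and 1622 had an unadjusted p under 0.05. edgeR called 4 higher and 8 lower and DESeq2 292 and 191. Hnrnpab was listed at 0 in si-Control and stood at 162 and 150 CPM (limma adjusted p = 6.14e-06). Oas1g was listed at 0 in si-Control and stood at 24.1 and 11.4 CPM (limma adjusted p = 0.0178). Wbp11 was listed at 0 in both libraries labelled si-Jun (limma adjusted p = 1.69e-04). Nhp2, a gene of small nucleolar ribonucleoproteins, stood at 11 and 16.2 CPM in si-Control and was listed at 0 in both (limma adjusted p = 0.0139). Of the called genes only AC111885.1 was not listed at 0 in any library. It stood at 107 and 120 CPM in si-Control and at 2.40 and 1.38 CPM in the libraries labelled si-Jun. Without all-or-none genes the counts were 0 higher and 1 lower, and without 1 library they ran from 6 to 486 higher and from 6 to 90 lower. Changes that did not pass included Penk (log2 −1.95, SE 0.239, limma adjusted p = 0.122), Mest (−1.42, 0.348), complement C4b (−1.52, 0.386) and the haemoglobin genes Hba-a2 (−1.60, 0.181) and Hbb (−1.64, 0.344). In the other direction were Cnn1 (2.62, 0.344), the sodium channel subunit gene Scn3b (2.59, 0.344), the desaturase gene Scd (2.34, 0.344), Sypl2 (2.20, 0.344) and Arid4b (2.99, 0.363), which was listed at 0 in si-Control replicate 2.

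**Figure D2:**
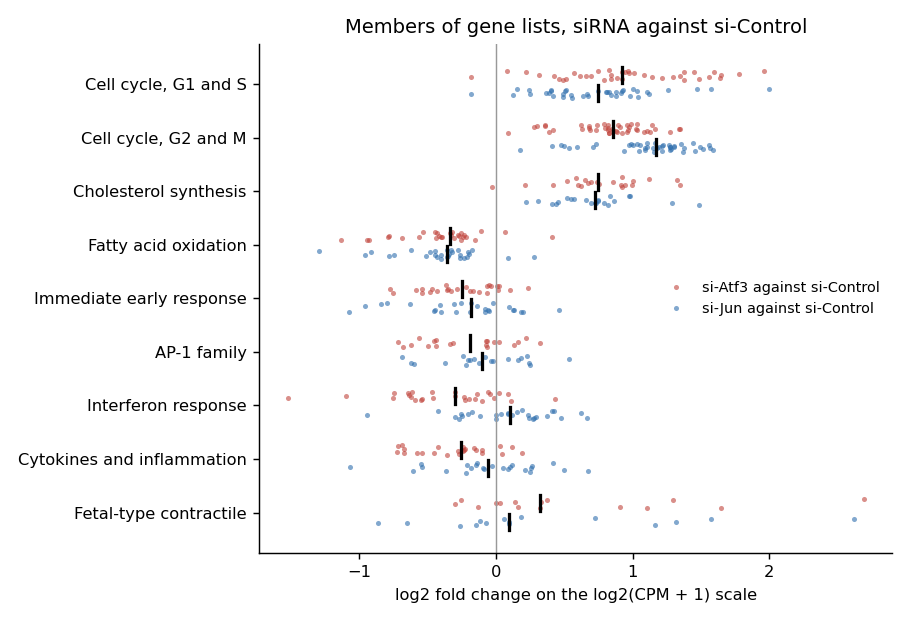
Log2 fold changes against si-Control of the measured members of 9 gene lists; each point is a gene, red for si-Atf3 and blue for the libraries labelled si-Jun, and black bars are list medians. Both cell cycle lists and cholesterol synthesis lie to the right of 0 and fatty acid oxidation to the left in both comparisons.

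Markers of other cell types tell how far the mixture of cells in the cultures moved. Besides the cardiomyocyte and macrophage markers given above, no marker list passed in either group under limma's camera with Benjamini-Hochberg adjustment. Fibroblast markers had medians of 0.10 in si-Atf3 (adjusted p = 0.810) and −0.09 in the libraries labelled si-Jun (0.208), and endothelial markers −0.16 (0.0979) and −0.18 (0.100). Mural markers, of pericytes and smooth muscle, had medians of −0.22 (0.258) and −0.11 (0.100), epicardial markers −0.15 (0.227) and −0.16 (0.100), and atrial markers 0.05 (0.793) and −0.09 (0.596). The 2 measured erythroid genes had medians of −1.11 and −1.62 and were too few for a test.

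Both si-Atf3 and the libraries labelled si-Jun were compared with the same si-Control libraries, and the question is how far their changes overlap. In both, 8 genes passed in the same direction, 4 higher and 4 lower, among them Hnrnpab, Oas1g and Wbp11. Of these 8, 7 were listed at 0 in both libraries of a group, and without all-or-none genes 1 gene was shared, while without 1 library the number ran from 7 to 438. The other gene of the 8 was AC111885.1, at 107 and 120 CPM in si-Control and 0.412 to 2.40 CPM elsewhere. This is above the limit of 0.1 CPM used for all-or-none genes. Its levels lay opposite to those of Hnrnpab, so it is not a shared call free of the counting question taken up below. Simulations of unchanged groups with shared simulated controls gave a mean of 0.02 over 50 draws. They held neither all-or-none genes nor correlation between genes, so they do not give the number that sharing these si-Control libraries produces. Independent lists of these sizes would share 0.0017 genes upward and 0.0026 downward. Across 13856 genes, which are not independent replicates, log2 fold changes correlated at 0.738 against 0.499 in the simulation. Their covariance was 0.119 against 0.0298, a difference of 0.0888. The controls cannot be divided with 2 libraries in each part, so part of the excess can come from them.

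The comparison of si-Atf3 with the libraries labelled si-Jun tests where these groups differ. Interferon genes were lower in si-Atf3, with a median log2 difference of −0.47 over 28 genes (limma camera with Benjamini-Hochberg adjustment, adjusted p = 4.84e-18; adjusted p = 0.480 with an estimated correlation), and 9 passed adjusted over the list alone. Rsad2 stood at 55.6 ± 8.09 CPM in si-Atf3, 136 ± 7.45 CPM in the libraries labelled si-Jun and 86.3 ± 15.3 CPM in si-Control (SD, n = 2). Ifit2 (−0.84), Herc6 (−0.78) and the peptide transporter gene Tap1 (−0.48) lay in the same direction. Macrophage markers were lower too, with a median of −0.32 (adjusted p = 2.10e-06; adjusted p = 0.383 with an estimated correlation), while cardiomyocyte markers were higher by a median of 0.13 (adjusted p = 0.0019; adjusted p = 0.289 with an estimated correlation) and fibroblast markers by 0.15 (adjusted p = 0.0404; adjusted p = 0.464 with an estimated correlation). The amino acid and unfolded protein responses were lower with a median of −0.29 (adjusted p = 1.13e-10; adjusted p = 0.480 with an estimated correlation), with the kinase-like gene Trib3 (−1.16), the cystine transporter gene Slc7a11 (−0.98), Gdf15 (−0.62) and Asns (−0.51). Cytokines were lower with a median of −0.21 (adjusted p = 3.61e-05; adjusted p = 0.480 with an estimated correlation), with Nos2 (−1.10), Lif (−1.04) and Cxcl1 (−0.91), while Mmp9 was at 0.61. Without si-Atf3 replicate 2 the interferon median was −0.31, and without si-Atf3 replicate 1 that of the amino acid response was −0.19.

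Smaller differences passed for other lists, and several rested on 1 library. G1 and S phase genes had a median of 0.27 (limma camera adjusted p = 3.79e-05; adjusted p = 0.751 with an estimated correlation), which turned to −0.09 without si-Jun replicate 2. G2 and M phase genes had a median of −0.28 (adjusted p = 2.19e-04; adjusted p = 0.823 with an estimated correlation), which turned to 0.28 without si-Jun replicate 1. Fetal-type genes (0.14, adjusted p = 0.00697), calcium handling (0.14, 0.00938), p53 targets (−0.16, 0.0222), the AP-1 family (−0.09, 0.0260) and adult sarcomere isoforms (0.16, 0.0369) passed with camera, and none of these did with an estimated correlation (adjusted p = 0.480 or 0.489 with an estimated correlation). Without si-Jun replicate 2 the medians of fetal-type genes and the AP-1 family turned to −0.12 and 0.02, and without si-Jun replicate 1 adult sarcomere isoforms (adjusted p = 0.127), calcium handling (0.919) and p53 targets (0.132) no longer passed with camera. Cholesterol genes were at 0.04 (0.496), but at 0.50 without si-Jun replicate 1 and at −0.37 without si-Jun replicate 2. Single genes that passed numbered 7, 4 higher and 3 lower in si-Atf3, in limma with Benjamini-Hochberg adjustment, with 569 at an unadjusted p under 0.05. edgeR called 3 higher and 3 lower and DESeq2 32 and 39. Without 1 library 1 to 3 of these 7 calls remained. They include Lilrb3a (log2 −3.23, SE 0.238, limma adjusted p = 0.0206), Nhp2 (limma adjusted p = 0.0206) and Sccpdh (limma adjusted p = 0.0207), the last listed at 0 in both libraries labelled si-Jun. Differences that did not pass included Mrps24 (1.36, limma adjusted p = 0.246), the fibrillin gene Fbn2 (1.26, 0.921), Cited1 (1.26, 1), Asb12 (1.11, 0.921) and Bmp3 (1.07, 0.921), and in the other direction Rsad2 (−1.29, 0.226), Kbtbd11 (−1.29, 0.643), Ccl3 (−1.32, 0.695), C1qc (−1.13, 0.705) and Trib3 (−1.16, 1).

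Genes that were higher at postnatal day 7 than at day 1 in cardiomyocyte-like cells were slightly lower in si-Atf3 and in the libraries labelled si-Jun. The reference list of ribosomal proteins fell by more in both (medians of −0.27 and −0.20). Only 94 genes were over 2-fold higher at day 7, so the set of 200 also holds smaller differences. The 200 genes higher at day 7 had a median log2 fold change of −0.08 in si-Atf3, with 116 of 200 below 0 (limma camera adjusted p = 0.00916; adjusted p = 0.457 with an estimated correlation). In the libraries labelled si-Jun the median was −0.11, with 122 of 200 below 0 (limma camera adjusted p = 1.10e-04; adjusted p = 0.242 with an estimated correlation), and it was −0.039 without si-Jun replicate 1. The 200 genes lower at day 7 had medians of 0.03 (0.166) and −0.0024 (0.458), the last with a mean of 0.06. Between si-Atf3 and si-Jun the sets had medians of 0.02 (0.126) and 0.04 (0.00182; adjusted p = 0.475 with an estimated correlation). Without si-Control replicate 1 the median of the day 7 set in si-Atf3 was −0.09 and camera's adjusted p 0.08.

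The single-cell libraries describe how the heart differed between postnatal days 1 and 7, with 1 library per day and no replicate check. Cardiomyocyte-like cells made up 32.6% of kept cells at day 1 (Clopper-Pearson interval 31.4 to 33.8) and 23.8% at day 7 (22.7 to 24.9). Fibroblast-like cells made up 11.5% (10.7 to 12.4) and 37.9% (36.6 to 39.1), endothelial-like cells 4.95% and 7.31%, and macrophage-like cells 3.04% (2.62 to 3.52) and 8.23% (7.55 to 8.95). Atrial-like cardiomyocytes made up 1.73% and 0.217%. Their summed atrial markers stood at 45051 CPM at day 1 and 7027 CPM at day 7, so the naming of the 13 day 7 cells is uncertain. The cluster led by mast cell genes is not compared, since its summed mast markers stood at 8.67 CPM at day 1 and 3887 CPM at day 7, so that its day 1 cells are not mast cells. Unnamed clusters held 33.8% and 15.4%, of which clusters with few UMIs and cardiomyocyte markers held 21.9% and 9.75% of all kept cells. With those added the cardiomyocyte-like share was 54.4% at day 1 and 33.5% at day 7, and with low-UMI clusters left out it was 14.2% at day 7, where 575 cells of the class come from a low-UMI cluster. Barcodes above the mitochondrial limit were left out, 34.1% at day 1 and 52.5% at day 7, and this limit moves the cardiomyocyte share, which was 25.8% and 18.5% at a limit of 20% and 4.52% and 31.5% with none.

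In cardiomyocyte-like cells, genes for adult contraction and fatty acid use were higher in the day 7 library, and fetal-type and glycolysis genes were lower. Among 4394 genes compared, 94 were over 2-fold higher and 84 over 2-fold lower at day 7. The counts were 128 and 63 when rescaled by the median ratio, 154 and 89 with a total without mitochondrially encoded and haemoglobin genes, 77 and 722 at a mitochondrial limit of 20%, 111 and 628 with no limit, and 94 and 135 with thinning. Myom2, which encodes a protein of the sarcomere's M band, stood at 4.86 CPM at day 1 and 50.3 CPM at day 7. Also higher were Rxrg (12.5 to 66.7 CPM), a retinoid receptor, Ech1 (116 to 416 CPM) of fatty acid oxidation, the sarcomeric protein gene Cmya5 (29.5 to 100 CPM), Fgf1 (32.8 to 112 CPM) and Pcp4l1 (32.1 to 114 CPM). Lower at day 7 were the growth factor gene Igf2 (112 to 18.7 CPM), the glucose transporter Slc2a1 (96.4 to 24.5 CPM), the lactate transporter Slc16a3 (62.8 to 16.3 CPM), the natriuretic peptide Nppb (2677 to 851 CPM) and the stress-responsive Ankrd1 (3398 to 1113 CPM). Ctgf (684 to 216 CPM), Gsn (257 to 70.8 CPM), Nuak1 (121 to 37.8 CPM), Aif1l (76.6 to 17.7 CPM) and Ddah1 (176 to 62.4 CPM) were lower as well. The matrix genes Dpt (11.3 to 69.7 CPM), Eln (15.0 to 69.2 CPM) and Fbn1 (16.7 to 63.3 CPM) and the antigen presentation gene Cd74 (26.6 to 85.2 CPM) were higher in these cells, where the summed fibroblast markers stood at 401 and 1050 CPM and the macrophage markers at 28.1 and 59.6 CPM. The largest cluster of the class differed between days, cluster 7 at day 1 (1434 of 1882 cells) and cluster 27 at day 7 (711 of 1424 cells), and Cmya5, Fgf1 and Myom2 lead cluster 27 while Nppb and Ankrd1 lead cluster 7.

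The fixed lists in cardiomyocyte-like cells followed the same lines. Fatty acid uptake and oxidation had a median log2 ratio of 0.58 over 26 genes, at the percentile 100 of random lists, with 2 members over 2-fold higher, Decr1 (82.3 to 174 CPM) and Acot2 (40.3 to 99.6 CPM), and with Fabp3, the cytosolic fatty acid carrier, at 1300 and 2241 CPM. Adult sarcomere isoforms had a median of 0.24 over 14 genes (percentile 99.98), with 4 over 2-fold higher, among them Myom2 and Xirp2 (91.9 to 275 CPM), and adult myosin Myh6 at 3840 and 7451 CPM. Mitochondrially encoded genes had a median of 0.25 (percentile 100) and took 28.4% of the class's UMIs at day 1 and 32.6% at day 7. Calcium handling had a median of 0.13 (percentile 99.5), with Pln at 4968 and 5358 CPM and Atp2a2 at 3769 and 3695 CPM. Fetal-type genes had a median of −0.59 over 14 genes (percentile 0), with 5 over 2-fold lower, among them Myl4 (1115 to 225 CPM), Myl7 (847 to 152 CPM) and Cnn1 (52.5 to 21.9 CPM), and fetal myosin Myh7 at 9532 and 5842 CPM. Myl4, Myl7 and Nppa (2568 to 1947 CPM) are also atrial markers, whose sum in these cells stood at 4544 and 2344 CPM beside the lower share of atrial-like cells at day 7, so part of this difference may come from atrial transcripts. Glycolysis had a median of −0.84 over 16 genes (percentile 0), with Aldoa (2468 to 1373 CPM) and Ldha (1913 to 1044 CPM) and, over 2-fold lower, Pgam1 (288 to 111 CPM) and Pfkl (41.6 to 18.2 CPM).

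Other lists stood apart less firmly in cardiomyocyte-like cells. Collagens and matrix had a median of 0.73 over 19 genes (percentile 100), beside the higher fibroblast markers. The AP-1 family had a median of 0.22 over 8 genes (percentile 99.4), and G2 and M phase genes 0.09 over 34 genes (percentile 99.96), with Top2a at 141 and 162 CPM. p53 targets had a median of −0.42 over 9 genes (percentile 0.65), with the polo-like kinase gene Plk2 at 127 and 55.9 CPM, and cholesterol synthesis −0.37 over 8 genes (percentile 2.16). Within the central 95% of random lists were ion channels (0.02), oxidative phosphorylation (−0.06), AP-1-linked targets (−0.07), regulators (−0.09), immediate early genes (−0.09), the amino acid response (−0.12), ribosomal proteins (−0.15), the tricarboxylic acid cycle (−0.20) and G1 and S phase genes (−0.22). Of the 11 lists outside the central 95%, fatty acid oxidation, fetal-type genes and glycolysis stayed outside on the same side under every alternative. Mitochondrially encoded genes came inside at resolution 0.5 (0.14), with doublets kept (0.15) and at a mitochondrial limit of 20% (0.019), a limit that acts on these genes themselves. Calcium handling came inside at resolution 0.5 (0.022), with at least 1000 genes (0.089), with doublets kept (0.026) and with thinning (0.090). The AP-1 family came inside with a total without mitochondrially encoded and haemoglobin genes (0.023), at resolution 0.5 (0.13), with doublets kept (0.12) and with thinning (0.15), p53 targets at resolution 0.5 (−0.29) and cholesterol synthesis with each library clustered on its own (−0.31), among other alternatives, and adult sarcomere isoforms at 20% (0.21). With a mitochondrial limit of 20% the medians of calcium handling, the AP-1 family, collagens, and G2 and M phase genes turned to −0.74, −0.76, −0.64 and −0.84. G2 and M phase genes also turned at resolution 0.5 (−0.072), with doublets kept (−0.041), with thinning (−0.21) and with no limit (−3.08), and collagens with no limit (−0.21). The interferon and cytokine lists had 1 and 4 members to compare and were left out.

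**Figure D3:**
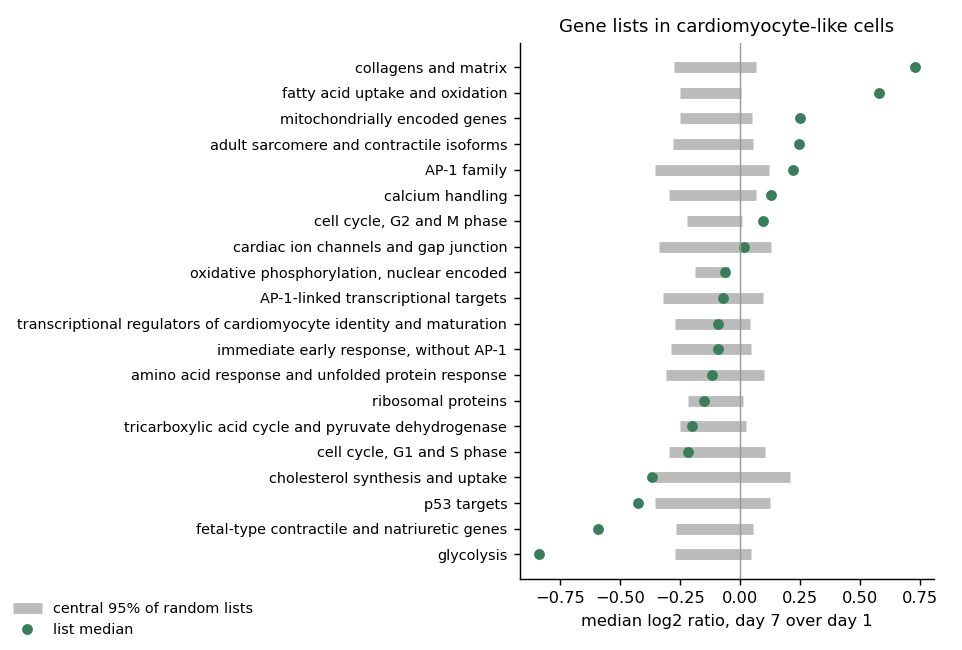
Median log2 ratio of day 7 over day 1 for 20 gene lists in cardiomyocyte-like cells (points), with the central 95% of 10000 random lists matched on size and expression (grey bars). Fatty acid oxidation (0.58) lies above its bar and fetal-type genes (−0.59) and glycolysis (−0.84) lie below theirs.

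UMIs of AP-1 factors were counted in each of the 4 cell classes compared, and the day ratios are given by class without a test, since there is 1 library per day. Part of such UMIs can come from RNA of other cells, as the summed cardiomyocyte markers stood at 1978 and 2174 CPM in fibroblast-like cells. In cardiomyocyte-like cells Atf3 stood at 218 CPM at day 1 and 196 CPM at day 7, a ratio of 0.90 (0.86 to 0.94). Jun stood at 367 and 520 CPM, a ratio of 1.42 (1.38 to 1.46). Fos (276 and 456 CPM), Fosb (94.9 and 224 CPM) and Junb (136 and 212 CPM) were higher at day 7, and Jund (209 and 190 CPM) was lower. Fosb was over 2-fold apart in this class. In fibroblast-like cells Atf3 stood at 217 and 625 CPM (ratio 2.88) and Jun at 769 and 1983 CPM (2.58). In endothelial-like cells Atf3 stood at 263 and 360 CPM and Jun at 692 and 1191 CPM, and in macrophage-like cells Atf3 at 144 and 628 CPM and Jun at 433 and 453 CPM. The immediate early gene Egr1, which tissue dissociation is known to induce, stood at 979 and 882 CPM in cardiomyocyte-like cells. With a mitochondrial limit of 20% the log2 ratio of Jun in cardiomyocyte-like cells turned from 0.50 to −0.76 and that of Atf3 moved from −0.15 to −2.00. With no such limit Atf3 was no longer lower at day 7. In the cells of the class at or below 20% Fos stood at 321 CPM at day 1 and 211 CPM at day 7, the opposite direction.

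**Figure D4:**
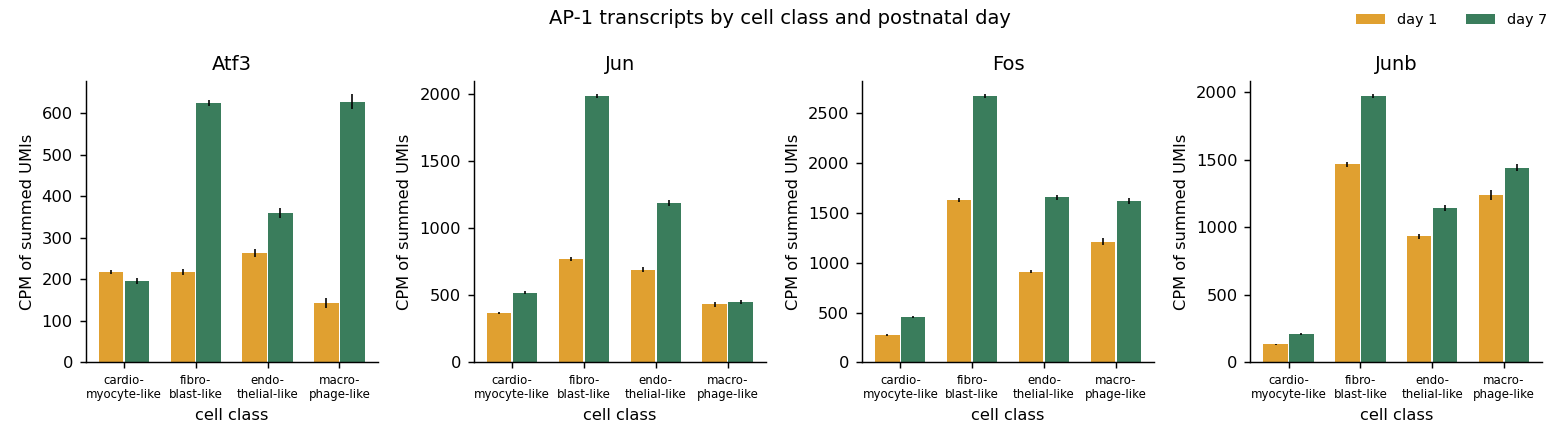
CPM of summed UMIs for Atf3, Jun, Fos and Junb in 4 cell classes at postnatal day 1 (orange) and day 7 (green), with exact 95% Poisson intervals that cover counting error only. Atf3 is at 218 and 196 CPM in cardiomyocyte-like cells and at 217 and 625 CPM in fibroblast-like cells.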

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

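The tests of 1 control library, of cell mixture, of genes split within a group and of the cluster that day 7 cells come from were chosen after the results were seen. The list of interferon genes stood out because si-Atf3 and the libraries labelled si-Jun differed in a test of the difference, with a median of −0.47 (limma camera adjusted p = 4.84e-18; adjusted p = 0.480 with an estimated correlation). Macrophage markers were lower in si-Atf3 in the same comparison (median −0.32). A smaller share of macrophages there cannot be told apart from a lower interferon response, and neither was tested. Between the same groups 7 genes differed, among them Lilrb3a, Nhp2 and Sccpdh, and 1 to 3 of these calls remained without 1 library. Barcodes above the mitochondrial limit made up 34.1% of barcodes at day 1 and 52.5% at day 7. Of these, 1898 of 3608 at day 1 and 4751 of 7435 at day 7 also had under 500 genes and entered no comparison. The rest could enter only the alternative with no limit.

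Hnrnpab, Wbp11 and other called genes were listed at 0 in whole transfection groups and at clear levels elsewhere. Gene counting that puts the same reads under different gene names could account for this, as 92 genes are at 0 in 1 library and at 5 CPM or more in the other of the same group, where the siRNA is the same. Of 32 genes with such 0s in 2 or 4 libraries, 34.4% had them fill whole groups (exact 95% interval 18.6 to 53.2), where chance gives 20%, so a switch by the siRNAs and chance cannot be told apart for these genes. AC111885.1 stood at 107 and 120 CPM in si-Control and at 0.412 to 2.40 CPM in the 4 libraries where Hnrnpab was at 150 to 172 CPM. Wbp11l1 stood at 45.9 to 49.8 CPM in the 4 libraries where Wbp11 was listed at 0. In si-Control it was at 0 in replicate 1 and at 38.0 CPM in replicate 2. Such opposite levels are what reads counted under another name would give. Without an annotation it was not checked that these names share reads, so both explanations stay open for the called genes.

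Cell cycle lists were higher and fatty acid oxidation lower in si-Atf3 and the libraries labelled si-Jun, where Jun itself was not clearly lower, and these calls were lost with an estimated correlation (limma camera adjusted p of 0.406, 0.435 and 0.406, and of 0.603 for each). A single control library as the cause is argued against, since all 6 medians kept at least 87.6% of their value without either one, but without si-Jun replicate 1 the G2 and M median there was 0.59 in place of 1.17. More non-myocytes in the si-Atf3 cultures would lower cardiomyocyte markers, which instead rose by a median of 0.63 (limma camera adjusted p = 1.67e-04; adjusted p = 0.191 with an estimated correlation; fry adjusted p = 0.0266). This does not exclude a shift in cell mixture, since marker levels per cell can change and fibroblast markers were at 0.10. In the libraries labelled si-Jun the median of cardiomyocyte markers was 0.14 (limma camera adjusted p = 0.107), so a shift in cell mixture cannot be told apart from a response there. A difference of both si-Control cultures from the 4 others and a response to the siRNAs stay open and were not tested.

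The direction of Jun between days in cardiomyocyte-like cells turned with the mitochondrial limit. Renamed clusters at the lower limit are argued against as the cause of the turn. The log2 ratio of Jun was −0.49 (−0.71 to −0.27) in the same cells without those above 20%, and that of Atf3 −0.99 (−1.35 to −0.66). Both fell further with the cells clustered anew at 20%, so renamed clusters may add to the size. Low-UMI cells could account for the turn of Jun. Of day 7 cells at or below 20%, 93.4% (254 of 272) belong to a low-UMI cluster, against 14.0% at day 1 (37 of 265). Whether Jun follows a cell's mitochondrial share stays open, since cells above 20% had 0.946 times the Jun of the others at day 1 and 1.94 times at day 7, and these cannot be told apart from a change with age. Age was not tested, with 1 library per day.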

How the results depend on the processing

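Leaving out all-or-none genes, leaving low-UMI clusters unnamed, out or added, and the alternatives for shared calls were chosen after the data were seen, and the other alternatives given here before the data were examined. Atf3 in si-Atf3 and Jun in si-Jun counted as the same in all 24 comparisons with an alternative. For Jun this does not show a stable direction. In si-Jun replicate 1 it stood at 94.9 CPM, between the si-Control libraries (91.3 and 97.8 CPM), and only replicate 2 (75.4 CPM) lay below both. Of 528 list medians in the bulk libraries 415 were the same and 9 reversed, and of 219 in the single cells 172 were the same and 9 reversed. On log2 values simulated gene by gene with the fitted spread and this group size, limma found 69 of 100 genes changed 2-fold. Read depth and correlation between genes did not enter, so this share need not hold in the data. Penk, 3.92-fold lower in si-Atf3, did not pass there (limma adjusted p = 0.115). The cause of the differences below was not tested.

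Genes higher in si-Atf3 (6) numbered 3 with a filter of 5 CPM, 26 with only the 4 libraries compared, 298 with DESeq2 and 0 without all-or-none genes, and from 4 to 537 without 1 library. Genes lower in si-Atf3 (6) numbered 202 with DESeq2 and 2 without all-or-none genes, and from 7 to 153 without 1 library. In the libraries labelled si-Jun genes higher (4) numbered 292 with DESeq2 and 0 without all-or-none genes, and from 6 to 486 without 1 library. Genes lower (6) numbered 191 and 1, and from 6 to 90. Between si-Atf3 and si-Jun, genes higher (4) numbered 2 with no filter, 2 with 5 CPM, 32 with DESeq2 and 0 without all-or-none genes, and from 1 to 13 without 1 library. Genes lower (3) numbered 0 with a pseudocount of 5, 0 with no filter, 1 with 5 CPM, 9 with the 4 libraries, 39 with DESeq2 and 1 without all-or-none genes, and from 1 to 5. The highest counts against si-Control came without si-Control replicate 1. With a replicate block, 1 gene was higher and 0 lower between si-Atf3 and si-Jun, and it moved no other count by over 1.5 times. Replicate numbers did not pair, with residual correlations of 0.12, −0.19 and −0.04. Shared calls (8) numbered 5 with 5 CPM, 1 without all-or-none genes and from 7 to 438 without 1 library.

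Lists passing (12, 8 and 10) numbered 0, 0 and 0 with camera and an estimated correlation and 0, 0 and 0 with fry. Without 1 library they numbered from 10 to 14, from 9 to 10 and from 6 to 13. The medians of oxidative phosphorylation ran from −0.25 to 0.14 in si-Atf3 and from −0.24 to 0.15 in si-Jun without 1 library, and ribosomal proteins in si-Jun from −0.41 to 0.0012. Between si-Atf3 and si-Jun they ran from −0.11 to 0.073 for fatty acid oxidation, −0.85 to 0.28 for G2 and M phase, −0.12 to 0.40 for fetal-type genes, −0.087 to 0.60 for G1 and S phase, −0.29 to 0.020 for the AP-1 family and −0.37 to 0.50 for cholesterol synthesis. Genes higher at day 7, with medians of −0.084 in si-Atf3 and −0.11 in si-Jun, lost their calls (limma camera adjusted p = 0.457 with an estimated correlation and adjusted p = 0.242 with an estimated correlation). Without 1 library they ran from −0.089 to −0.061 in si-Atf3, and genes lower at day 7 from 0.033 to 0.089 in si-Atf3 and from −0.050 to 0.084 in si-Jun. Between si-Atf3 and si-Jun the day 7 set had 0.020 with 100 genes and ran from −0.047 to 0.071 without 1 library, and genes lower at day 7 had 0.038 (adjusted p = 0.475 with an estimated correlation) and ran from −0.029 to 0.090.

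In the single cells the settings, in order, were Leiden resolution 0.5, at least 1000 genes, doublets kept, each library clustered on its own, a mitochondrial limit of 20% and none. The cardiomyocyte-like share at day 7 was 30.7%, 21.9%, 28.7%, 22.3%, 18.5% and 31.5%, and at day 1, from at least 1000 genes on, 37.3%, 30.8%, 38.2%, 25.8% and 4.52%. With low-UMI clusters left out it was 14.2% at day 7, and with those of cardiomyocyte markers added 54.4% and 33.5%. Atf3 (−0.15) had log2 ratios of −0.31, −0.23, −0.32, −0.074, −2.00 and 0.016 in that order, and Jun (0.50) of 0.37, 0.41, 0.34, 0.58, −0.76 and 0.37. With a total without mitochondrially encoded and haemoglobin genes, the median ratio, thinning and low-UMI clusters left out, Atf3 had −0.066, −0.033, −0.48 and −0.064 and Jun 0.59, 0.62, 0.34 and 0.59. Genes over 2-fold lower numbered 722 at 20%, 628 with no limit and 135 with thinning, and genes higher 154 with the total without mitochondrially encoded and haemoglobin genes. Lists above the central 95% of random lists (7) numbered 3 at resolution 0.5, 3 with doublets kept, 1 at 20% and 4 with thinning, and lists below it (4) numbered 9 at 20%. G2 and M phase genes turned to −0.072 at resolution 0.5, −0.041 with doublets kept, −0.84 at 20%, −3.08 with no limit and −0.21 with thinning. At 20% calcium handling turned to −0.74, the AP-1 family to −0.76 and collagens to −0.64, and with no limit collagens to −0.21.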

Other observations

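Interferon-induced genes were higher at day 7 than at day 1 in the non-myocytes of the heart. The interferon list had a median log2 ratio of 2.48 over 6 genes in fibroblast-like cells, 1.87 over 21 genes in endothelial-like cells and 1.19 over 15 genes in macrophage-like cells, each at percentile 100 of random lists. Isg15, a ubiquitin-like antiviral protein gene, stood at 0.835 and 66.1 CPM in fibroblast-like cells and at 4.38 and 84.5 CPM in macrophage-like cells. In endothelial-like cells Mx2 stood at 8.78 and 113 CPM. Small clusters led by interferon genes hold part of this. Without them only 2 genes of the list could be compared in fibroblast-like cells, too few for a median, and Isg15 stood there at 0.0557 and 9.01 CPM. The endothelial-like median without them was 1.11 over 14 genes, with Isg15 at 26.2 and 102 CPM. There is 1 library per day, so litter, infection and age are not separated.

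Fibroblast-like cells had lower levels of cell cycle genes at day 7. The list of G2 and M phase genes had a median log2 ratio of −0.95, with 15 of 38 members over 2-fold lower, and G1 and S phase genes −0.66. The growth regulator gene Dlk1 stood at 325 and 7.65 CPM in these cells, and PCOLCE2, which aids collagen processing, was higher, at 1.34 and 82.2 CPM. In endothelial-like cells Car4, a carbonic anhydrase gene of capillaries, stood at 16.3 and 254 CPM, and the glucose transporter gene Slc2a1 at 93.2 and 15.3 CPM. In macrophage-like cells the lectin gene Clec4f stood at 92.3 CPM at day 1 and 0 UMIs at day 7, Spp1 at 835 and 77.3 CPM, and the chemokine gene Ccl12 at 14.7 and 198 CPM. Glycolysis was lower at day 7 in fibroblast-like (−1.04), endothelial-like (−1.17) and macrophage-like cells (−1.08), as in cardiomyocyte-like cells. Fatty acid uptake and oxidation had medians of 0.31, 0.40 and 0.16 in these classes (percentiles 99.5, 99.95 and 85.2), beside 0.58 in cardiomyocyte-like cells. Fetal-type genes had medians of −0.68, −0.79 and −0.57 and mitochondrially encoded genes of 0.28, 0.41 and 0.34 in the same 3 classes, where the summed cardiomyocyte markers stood at 1978 and 2174, 2474 and 2076, and 2644 and 2364 CPM at days 1 and 7. Collagens and matrix had medians of 0.41 in fibroblast-like cells, and of 0.56 in endothelial-like and 0.44 in macrophage-like cells, where the summed fibroblast markers stood at 897 and 1509 and at 694 and 1107 CPM. Glycolysis genes summed to 3117 and 1558, 4817 and 2390, and 6529 and 3381 CPM in fibroblast-, endothelial- and macrophage-like cells. In cardiomyocyte-like cells they summed to 8103 and 4769 CPM, beside 45887 and 45149 CPM of cardiomyocyte markers. These sums argue against free RNA of cardiomyocytes as the main source of the lower glycolysis. Outside that and the collagens of fibroblast-like cells, the values do not tell expression in the named cells from free RNA of cardiomyocytes or fibroblasts.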
